A study of Mus musculus with 4 samples.

How the data were processed

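Brain endothelial cells of the mouse hippocampus were profiled with droplet-based single-cell RNA sequencing. There were 4 libraries, 1 for each of the groups Young, Aged, Gpld1 and TNAPi, and each library came from a pool of 8 mice, per the labels' protocols. Young and Aged were controls, Gpld1 stands for aged mice in which the liver expressed GPLD1, and TNAPi stands for aged mice given an inhibitor of TNAP. Live cells that carried the endothelial surface protein CD31 and lacked CD45 (leukocytes) and CD41 (platelets) were sorted, and 20000 cells were loaded per library, per the labels' protocols.

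Count matrices were made with Cell Ranger 7.1, per the labels' protocols, and the genome build is mm10, per the submitters' processing notes. The software version could not be checked here. It is in doubt from the structure of the barcodes, but only through background knowledge that was not tested here. The build is in doubt from the gene order of the lists. The annotation release, the chemistry version of the kit and any filter on cells after Cell Ranger are not given in the sources used here. The deposited files used here were 2 text lists per library. The first holds the cell barcodes of the filtered matrix, each with 16 bases, and the second holds the gene ID, gene symbol and feature type of every row of that matrix. Neither list holds a measurement per gene or per cell. The matrices of UMI counts were not analysed here, so no expression level, sequencing depth, cell type or doublet call was computed, and the comparisons of expression planned before the data were examined were not run.

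Each library's barcodes were counted, with an exact 95% Poisson interval. Ratios between libraries have an exact 95% interval from the binomial share of their summed barcodes. These intervals cover counting error only and say nothing about the variation between mice, pools, sorts or captures. With 1 library per group, no test between groups was made. Barcodes were compared between libraries by exact match of their bases. The number expected to be shared by chance was computed from the barcode pool that the lists themselves show, in which bases 8 and 9 define 4 blocks and each barcode joins a start of 7 bases to an end of 7 bases of its block.

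Gene IDs were matched to GENCODE M21, an annotation of the GRCm38 assembly (mm10). Of 33696 IDs, 32012 matched (95.0%). The feature list gives no coordinates, so those printed are GRCm38 coordinates of GENCODE M21, counted from 1, and need not be the ones used for counting. For each chromosome, the matched genes were taken in list order. The largest set of them whose GRCm38 start positions never fall along that order was found, and genes that break the order were skipped. This set is called the longest run of rising start positions, and the number of genes outside it was counted. The named genes are those of 10 gene lists and 12 lists of cell type markers, fixed before the data were examined. A rule of that plan for the genes with the largest expression differences could not be applied.

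The alternatives were leaving out barcodes also listed in another library, and counting barcodes 1 base apart as shared. The calculations were tested on simulated data. In a simulation of the 6 pairs of libraries, 100.0% of the simulated pool was recovered and the interval held the expectation for 6 pairs. These barcodes were drawn evenly from a pool built as the calculation assumes, with no carry-over. The simulation therefore checks the calculation and not its power to detect carry-over. In a list of 1000 simulated genes with a reversed block of 150, 149 displaced genes were found, as many as a reversal displaces. Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used.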

Results

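Sorted endothelial cells of the hippocampus gave 83224 listed cell barcodes over the 4 libraries. A cell barcode is the short sequence shared by all transcripts captured in one droplet, and those listed are the ones called as cells. The Young library listed 19118 barcodes (exact 95% Poisson interval 18848 to 19391), and the Aged library listed 23951 (23649 to 24256). The Gpld1 library listed 15965 (15718 to 16215), and the TNAPi library listed 24190 (23886 to 24497). Each group had 1 library from a pool of 8 mice, so no value has a replicate error. UMI counts were not analysed here, and the depth per cell behind these barcodes is unknown.

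Every barcode was distinct within its library. Set against the 20000 cells loaded per library, the number of barcodes came to 95.6% in Young and 79.8% in Gpld1. It came to 119.8% in Aged, 3951 barcodes above the number loaded, and to 121.0% in TNAPi, 4190 above it. These are ratios and not shares of the loaded cells, since a listed barcode need not stand for one loaded cell. Nor need every loaded cell give a listed barcode. A number below 20000, as in Young and Gpld1, therefore does not show that a library matched the stated loading.

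**Figure D1:**
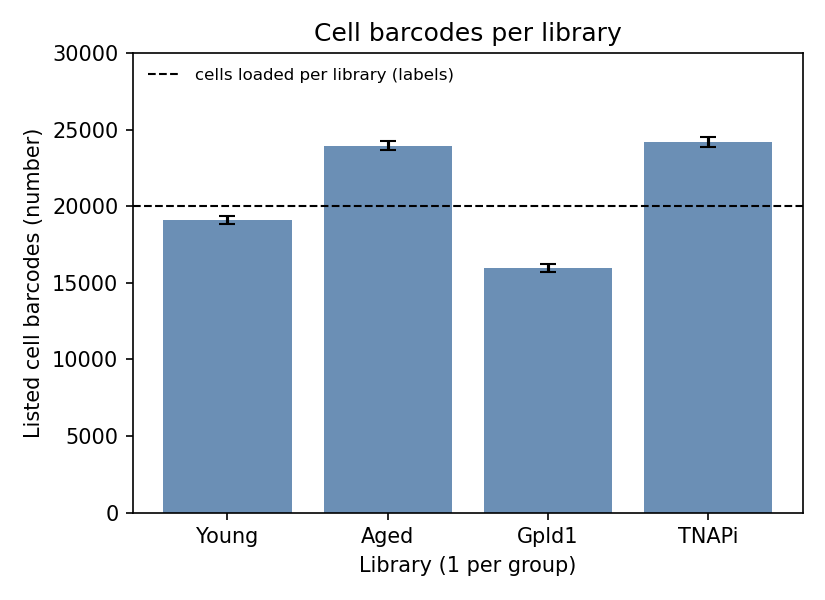
Listed cell barcodes (number, y axis) in each library (x axis, 1 library per group), with exact 95% Poisson intervals as error bars and the 20000 cells loaded as a dashed line. The Aged (23951) and TNAPi (24190) bars stand above the line, and the Young (19118) and Gpld1 (15965) bars below it.

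The comparison of Aged with Young mice addresses what age does to hippocampal endothelial cells. The Aged library listed 4833 more barcodes than the Young library, a ratio of 1.253 (exact 95% interval 1.229 to 1.277). That interval excludes a ratio of 1 as far as counting error goes. The number of barcodes is set by sorting, loading, capture and cell calling, and it is no measure of how many endothelial cells a hippocampus holds.

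The Gpld1 library addresses what GPLD1 made by the liver does to the endothelium of aged mice. It listed 7986 fewer barcodes than the Aged library (15965 against 23951), a ratio of 0.667 (0.653 to 0.680). The TNAPi library addresses the inhibition of TNAP, the enzyme encoded by Alpl, in aged mice. It listed 239 more barcodes than the Aged library (24190 against 23951), a ratio of 1.010 (0.992 to 1.028), and that interval holds a ratio of 1. The Gpld1 library listed 8225 fewer barcodes than the TNAPi library, a ratio of 0.660 (0.647 to 0.673). None of these differences could be set against a spread between replicates. The Gpld1 and TNAPi ratios to Aged also rest on the same Aged library. Here too the number of barcodes is set by sorting, loading, capture and cell calling. These ratios therefore measure no effect of either treatment on the endothelium.

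The genes at the centre of the study were both among the rows of the count matrices. Gpld1 (ENSMUSG00000021340), which encodes a phospholipase that cleaves GPI-anchored proteins from the cell surface, is a protein-coding gene on the plus strand of chromosome 13, from 24943152 to 24992501 in GRCm38. Alpl (ENSMUSG00000028766), which encodes tissue-nonspecific alkaline phosphatase, a GPI-anchored enzyme, is a protein-coding gene on the minus strand of chromosome 4, from 137741733 to 137796384. No row stands for a transgene, a vector or a human gene, since all 33696 IDs are mouse Ensembl gene IDs. The matrices thus have no separate row for an expression construct.

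Every gene of the fixed lists has a row in the matrices, and no level is given here. All 14 blood-brain barrier transport genes were listed, among them Slc2a1, the glucose transporter, Mfsd2a, a lipid transporter, Abcb1a, a drug efflux pump, and Plvap, a protein of fenestrated vessels. All 7 genes of the tight junction list had a row, including Cldn5 and Ocln. That list also holds Cdh5, which encodes the cadherin of endothelial adherens junctions. Rows were also present for the 7 arterial genes (such as Bmx and Gja5) and the 6 venous genes (such as Nr2f2 and Vcam1). The 8 inflammation genes, the 7 interferon genes, the 5 antigen presentation genes and the 7 immediate early genes were also complete. So were the 11 genes of GPI-anchored proteins and GPI synthesis, which include Ly6c1, Prnp, Car4, Cd55 and Piga.

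Markers of the sort were listed as well. Pecam1, which encodes CD31, lies on the minus strand of chromosome 11, from 106654217 to 106750628 in GRCm38. Ptprc, which encodes CD45, lies on the minus strand of chromosome 1, from 138062861 to 138175708. Itga2b, which encodes CD41, lies on the minus strand of chromosome 11, from 102453297 to 102470122. The 8 endothelial markers and all markers of the 11 other cell types were listed, including Pdgfrb and Kcnj8 of pericytes, Acta2 of smooth muscle, P2ry12 of microglia, Aqp4 of astrocytes, Ttr of the choroid plexus and Hba-a1 of erythrocytes. Hba-a1 and Hba-a2 are near-identical copies, as are Hspa1a and Hspa1b, so counts of either member of these pairs would be uncertain.

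The 4 libraries had identical feature lists, all of the gene expression type. Of the 22028 protein-coding genes of GENCODE M21, 21409 were listed by ID (97.2%). A further 9803 listed genes have a long non-coding biotype there, and 697 are immunoglobulin or T cell receptor segments. Of 6015 genes for microRNA, small nuclear, small nucleolar, ribosomal and miscellaneous RNA, 0 were listed. Of 9941 processed pseudogenes, 5 were listed. The list held 13 mitochondrial genes. There were 26 symbols that stood on 2 IDs each, among them Aldoa, a glycolytic enzyme, Ddit3, a stress-response transcription factor, Nnt, a mitochondrial transhydrogenase, and Nrg1, a growth factor, all chosen after the list was seen. A table keyed by symbol would merge or rename these rows.

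The order of the genes in the list departed from GRCm38 start positions more often on chromosome 14 than on the other nuclear chromosomes. On chromosome 14, 151 of 1453 matched genes (10.39%) lay outside the longest run of rising start positions, against 32 of 30495 (0.10%) on the other 20 nuclear chromosomes. A block of 152 genes ran backwards (Spearman rho of list order against start, across genes, -0.9999), from Gm48099, which starts at 19271274 in GRCm38, to Gm2888, which starts at 3030002. Of its 151 neighbouring pairs of genes, 16 went against falling start positions and 1 against falling end positions. Of the listed IDs, 1684 (5.0%) were absent from GENCODE M21. The genome build in the submitters' processing notes is mm10, which is GRCm38.

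**Figure D2:**
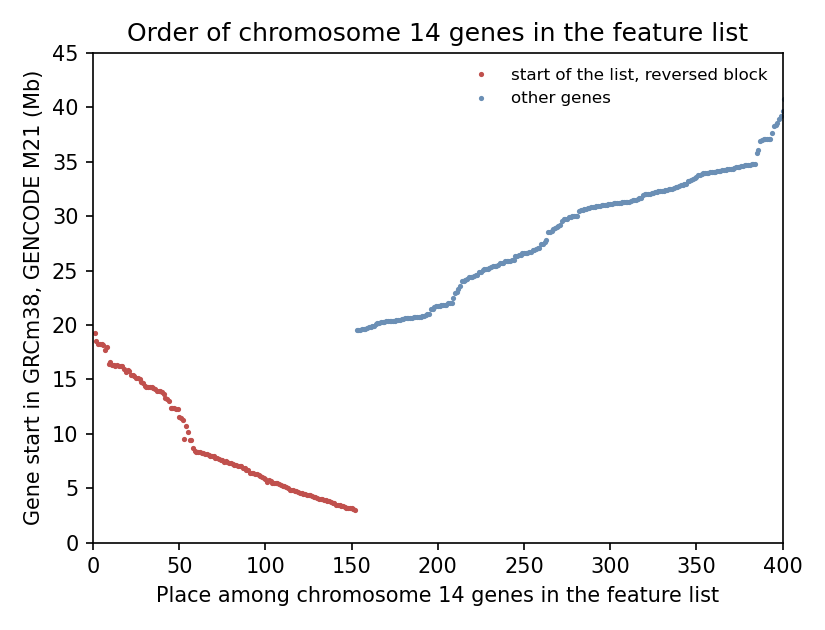
Start position in GRCm38 (Mb, y axis) of the first genes of chromosome 14 by their place in the feature list (x axis), 1 point per gene matched to GENCODE M21. The 152 genes of the first block run downwards from 19271274 to 3030002, and the genes after it run upwards.

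Sharing of barcodes between libraries was compared with chance for each of the 6 pairs. The Aged and TNAPi libraries shared 181 barcodes (exact 95% Poisson interval 156 to 209), where chance gives 157.2. Young and Aged shared 147 (124 to 173) against 124.3, and Young and TNAPi shared 137 (115 to 162) against 125.5. Aged and Gpld1 shared 106 (87 to 128) against 103.7, and Young and Gpld1 shared 77 (61 to 96) against 82.8. Gpld1 and TNAPi shared 84 (67 to 104) against 104.8, the 1 pair of 6 whose interval missed the expectation, from below. The miss is narrow, and 1 miss among 6 intervals at 95% can arise by chance. Summed over the 6 pairs, 732 were shared (680 to 787) against 698.3.

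**Figure D3:**
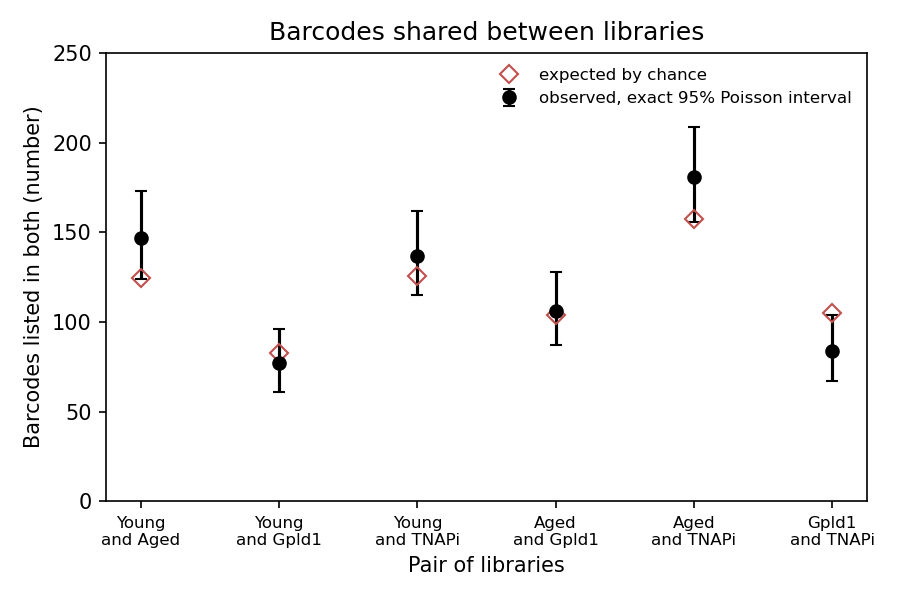
Barcodes listed in both libraries of each pair (number, y axis; pairs on the x axis), with exact 95% Poisson intervals as error bars, beside the number expected by chance (open diamonds). The intervals hold the expectation for 5 of the 6 pairs, and Gpld1 with TNAPi lies below it (84 against 104.8).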

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

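Leaving out barcodes that another library also listed can only lower a library's number. It came to 18764 in Young, 23525 in Aged, 15701 in Gpld1 and 23796 in TNAPi. Each of these lies below the library's counting interval, in Gpld1 just below its lower limit of 15718. The 4 ratios between libraries stayed within their intervals, and Aged and TNAPi stayed above the 20000 cells loaded. The setting removed a similar share of every library, from 1.63% in TNAPi to 1.85% in Young. It removed 426 Aged and 394 TNAPi barcodes, against 3951 and 4190 above the number loaded. Removals so small and so even could change neither outcome, so this is no test of stability. Counting barcodes 1 base apart as shared left all 6 numbers of shared barcodes as they were. That setting moved nothing, because 0 pairs of barcodes in the lists differ at 1 base, so it is no test of stability. No paired analysis was possible because each group has 1 library. No replicate could be left out for the same reason. Other settings for expression, cell filters, doublets, shares of cells per class and the reversal of age differences, fixed before the data were examined, were not run, since UMI counts were not analysed here. Depth could not be assessed.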

Other observations

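The tests of the ordered run of genes and of carried-over barcodes were chosen after their results had been seen, and those on RefSeq positions and gene ends after the reversed block had been seen but before their own results were. Splitting the RefSeq test by whether a gene has a RefSeq position was done after its result had been seen.

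The reversed block of 152 genes at the start of chromosome 14 in the feature list holds Thrb and Rarb, nuclear hormone receptors, Top2b, a topoisomerase, and Pdhb, a subunit of pyruvate dehydrogenase. A newer annotation release on the same assembly could add genes but not reverse a block of shared ones, and the 10.39% of matched chromosome 14 genes outside the ordered run argues against it as the whole cause. RefSeq, another annotation of GRCm38, gives a position to 120 of the 152 genes (78.9%), or to 115 (75.7%) by current symbol alone. Both lie under the minimum of 80% for a check of the whole block, and the genes were split for that reason. RefSeq start positions also fall along the block (Spearman rho across genes -0.99992) for the 120 genes, which argues against an error of GENCODE M21 in these. For the other 32 no RefSeq position was matched, and such an error stays open for these. An error confined to these 32 could not account for the fall of RefSeq positions along the 120. In addition, 1684 listed IDs (5.0%) are absent from GENCODE M21, 1329 of them with symbols of the Gm series, and 2635 matched IDs carry another symbol than in M21.

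If this segment is inverted between GRCm38 and the assembly behind the list, genes sorted by start there should come in the order of falling GRCm38 ends, not starts. Of 151 neighbouring pairs in the block, 1 went against falling ends (0.66%) and 16 against falling starts (10.6%), which is what an inversion predicts. A candidate explanation is therefore that reads were counted on GRCm39, the successor of GRCm38, which was not used here. Under that hypothesis, coordinates taken from mm10 may not apply to these matrices.

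The Aged and TNAPi libraries listed 3951 and 4190 more barcodes than the 20000 cells loaded. Barcodes carried over from the other 3 libraries would appear in more than 1 list. Only 426 Aged barcodes (exact 95% Poisson interval 387 to 468) and 394 TNAPi barcodes (356 to 435) did, which argues against carry-over as the whole cause. Most of these would be shared without any carry-over. Chance alone gives 124.3 for Aged with Young, 103.7 for Aged with Gpld1 and 157.2 for Aged with TNAPi. It gives 125.5 for TNAPi with Young and 104.8 for TNAPi with Gpld1. A larger number of cells loaded than stated, empty droplets called as cells, and droplets with more than 1 barcode may each play a part. These stay open and untested, since each needs the UMI counts or the loading record. No biological explanation was tested.

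The barcodes show how their pool was built. Bases 8 and 9, counted from the first base, were AG, CA, GT or TC in every barcode, and each pair went with its own set of starts and ends. There were 960 starts and 960 ends for each pair, except TC with 959 starts, and 0 starts or ends occurred with more than 1 pair. Joining every start to every end within each of the 4 blocks gives 3685440 barcodes. If sharing is by chance alone, the number of barcodes shared by the libraries implies a pool of 3515744 over the 6 pairs, and from 3114933 to 4597540 for single pairs. This restates the comparison of sharing with chance and is no independent support for either. Each block held between 24.6% and 25.5% of every library's barcodes. From background knowledge that no table here tests, this structure resembles the barcode pool of a kit generation that is believed to need a later Cell Ranger than the 7.1 in the labels. No barcode list of a kit version was used here, so the stated version could not be checked. The doubt about it rests on that background knowledge alone.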
